A study of Mus musculus with 11 samples.

How the data were processed

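RNA of sorted CD8 T cells was extracted with the Absolutely RNA Nanoprep kit and amplified with the Ovation Pico WTA kit, and biotin-labelled product was hybridised to microarrays, per the labels' protocols. Amplification of small amounts of RNA can add noise between arrays, and its size was not measured here. The authors deposited 1 table of log2 signals, with 115830 rows and 11 arrays and values from 1.27 to 14.4. The submitters' processing notes name RMA, a method that corrects background, normalizes and summarises probes, together with Partek and the genome build mm9. Versions, probe selection and the order of steps were not given in the sources used here. The log2 scale was read from the range of the deposited values.

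Rows were named through the platform's annotation. Of the rows, 25539 (22.0%) name 1 gene, 2300 name several and 87991 are unnamed here, and only rows with 1 gene were used for genes. The Entrez identifiers of 24941 of those rows were found in the RefSeq gene table, and no symbol needed an update. The rows name 20259 genes, of which 3109 have over 1 row. For each gene the row with the highest mean over all arrays was used. Genes with a mean under the 25th percentile of named genes (log2 signal 4.33) were left out, which left 15194 genes. Rows that name no gene or several, and lie at or above that filter value, were tested separately, with 0 of 44971 past the threshold in each comparison. Coordinates are not printed, since the gene table uses another assembly than the authors' build.

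Groups were taken from the genotypes of T cells and hosts in the labels. The main test was limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on the deposited values of all 11 arrays, group means alone in the model and Benjamini-Hochberg adjustment over all genes tested in a comparison, at an adjusted p under 0.05. No array was left out and the values were not normalized again. The labels do not say whether each array stands for 1 mouse or for pooled mice, so p-values measure the spread between these samples. No pair of arrays had more than 3 identical values, so none was deposited under 2 names. Single values were compared by exact two-sided permutation tests.

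The 23 gene lists, the rule for named genes and the design of the comparisons and list tests were fixed before the data were examined. Some tests of explanations and some alternatives were chosen later. Lists were tested with camera of limma at an inter-gene correlation of 0.01, adjusted over 69 tests (23 lists in 3 comparisons), again with an estimated correlation, and with fry, which tests whether genes of a list move one way on balance without comparing them with other genes. Members were counted past the threshold over all genes and adjusted over the list alone. The median of each list was placed among 10000 random lists matched on mean signal. A list's score in an array is the mean of its genes' log2 signals after subtracting each gene's mean over the arrays. Named genes were, per comparison, the 10 of lowest p in each direction since none passed, up to 4 members per list with the lowest p, Lgals3, and Lag3, Pdcd1, Ifng, Gzmb, Prf1, Cd8a and Thy1. Not every named gene is printed below. Ifng and Prf1 are not printed for the comparison between hosts, nor Cd8a and Thy1 for that between T cell genotypes. Cd68, Ctss and the neutrophil granule genes were named after their values were seen. Genes within 10 Mb of Lgals3 were to be named if past the threshold, and none was.

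The procedure was tested on simulated data with the means and spreads of the real genes. Of 200 changed genes among 15194, the share called in the comparison of WT T cells from KO and WT hosts was 10.4% at a log2 change of 0.5, 82.1% at 1 and 98.5% at 2. For KO T cells in KO hosts against WT T cells in WT hosts these shares were 19.4%, 83.6% and 100%, and for KO against WT T cells in KO hosts 7.46%, 82.1% and 98.5%. These shares hold for 200 changed genes of such sizes, and the adjustment is stricter where fewer genes change. Even there, changes of single genes near 0.5 were mostly out of reach. In the real data Lgals3, at -0.84 between T cell genotypes in KO hosts, did not pass (limma adjusted p = 0.661). The shares thus do not show that a real change of 1 or more would have been called. A list of 24 genes shifted by 0.3 was called in each of the 3 simulations, and 0 of 22 other lists were. The simulated genes vary independently, unlike real ones.

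Alternatives covered normalization, the filter, the rule for several rows, variance models, array weights, the samples in the fit, a block for replicate numbers, a fold change minimum, each array left out in turn, and list tests. Chosen after seeing the data were cyclic loess normalization, the value range, the macrophage score or a residual component as covariates, and the fit without the 2 arrays of narrowest range. An array's value range is its slope on the mean of all arrays. For comparisons sharing the reference arrays, 100 sets of unchanged groups were simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.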

Results

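Transcript levels were measured on 11 microarrays of mouse CD8 T cells that had been transferred into tumor-bearing mice and recovered from the tumors. The transferred cells came from T cell receptor transgenic donors and carried the congenic surface marker Thy1.2, by which they were sorted. Donors and hosts were either wild type (WT) or knockout (KO) for galectin-3. This secreted lectin binds galactose-containing glycans and is encoded by Lgals3. Hosts carried NT2.5 tumors, a mouse mammary tumor line. They received 100 mg/kg cyclophosphamide on day 8, a whole-cell vaccine secreting the cytokine GM-CSF on day 9 and T cells on day 10, and tumors were taken 5 days after the transfer. WT T cells from WT hosts were the reference group (n = 4), beside WT T cells from KO hosts (n = 3) and KO T cells from KO hosts (n = 4). The design speaks of 4 biological replicates per group, and the fourth array of WT T cells from KO hosts was not analysed here. Values were deposited log2 signals, and 15194 named genes entered the tests. Pairs of arrays correlated between 0.941 and 0.974 across genes, and the average was 0.963 within groups and 0.962 between groups. These small group sizes limited the precision of every value below, with a median SE of a log2 fold change of 0.15 to 0.16.

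Lgals3, on chromosome 14, was lower in every array of KO T cells than in every array of WT T cells. Its log2 signal was 8.31 ± 0.17 (SD, n = 4) in WT T cells from WT hosts, 8.27 ± 0.22 (SD, n = 3) in WT T cells from KO hosts and 7.43 ± 0.14 (SD, n = 4) in KO T cells from KO hosts. The difference between KO T cells in KO hosts and the reference group was -0.87 (SE 0.13), with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays allow. Its limma adjusted p was 0.103. Against WT T cells in the same KO hosts it was -0.84 (SE 0.14), with an exact two-sided permutation p of 0.0286, the smallest that 4 against 3 arrays allow. Lgals3 had the lowest p of all genes in that comparison (limma adjusted p = 0.661). In WT T cells the host genotype made a difference of -0.03 (SE 0.14; limma adjusted p = 0.950). The signal that remained in KO T cells lay between the 85.8th and the 88.7th percentile of named genes. The probe set (6818696) is the 1 row that names this gene. Where its probes lie relative to the deleted part of the gene was not given in the sources used here, so the remaining signal measures neither residual transcript nor background.

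**Figure D1:**
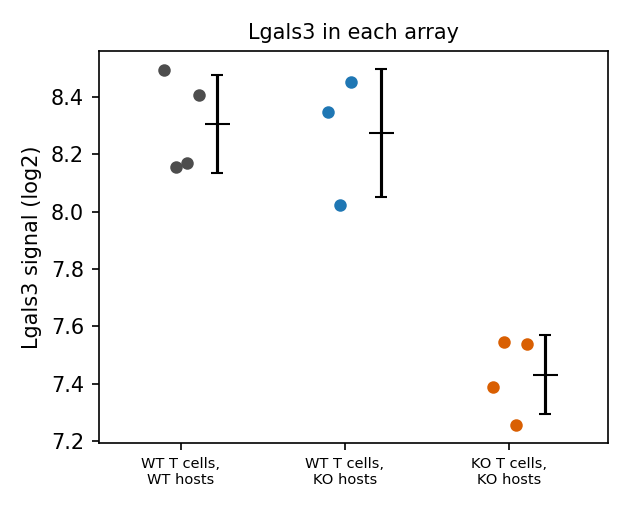
Lgals3 signal (log2, vertical axis) in each of the 11 arrays, by group on the horizontal axis. Points are arrays, and the horizontal mark with its bar is the mean ± SD; the vertical axis does not start at 0. The 4 arrays of KO T cells lie between 7.26 and 7.54, below all arrays of WT T cells, which lie between 8.02 and 8.49.

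The comparison of WT T cells from KO hosts with WT T cells from WT hosts asked what galectin-3 of the host changes in T cells of 1 genotype. Genes of the interferon gamma response and of antigen presentation rose together in KO hosts, by 0.30 on the log2 scale on average. Of 17 measured genes, 14 were higher (camera adjusted p = 5.78e-07; adjusted p = 0.0566 with an estimated correlation). The type I interferon response rose by 0.27 over 24 genes, 20 of them higher (camera adjusted p = 1.17e-05; adjusted p = 0.0639 with an estimated correlation). Markers of monocytes and macrophages, a cell type that the sort was meant to leave out, rose in the same arrays by 0.40 over 17 genes, 14 of them higher (camera adjusted p = 4.81e-08; adjusted p = 0.107 with an estimated correlation). Without array 3 of WT T cells from KO hosts the macrophage rise was 0.26 (camera adjusted p = 0.000209). Scores of these 3 lists were higher in each of the 3 arrays from KO hosts than in each of the 4 from WT hosts, each with an exact two-sided permutation p of 0.0286, the smallest possible here, which became 0.197 after adjustment over the 69 list scores.

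Within the interferon gamma list, Irf1, a transcription factor induced by interferon, had a log2 fold change of 0.64 (SE 0.16), the GTPases Irgm1 and Gbp3 had 0.59 (SE 0.15) and 0.54 (SE 0.15), and the chemokine Cxcl9, which attracts activated T cells, had 0.73 (SE 0.23). No member passed over all genes, and 5 passed when adjusted over the list alone. In the type I list, Ifit1 had a log2 fold change of 1.12 (SE 0.43), Parp14 of 0.59 (SE 0.18) and Oasl2, of the oligoadenylate synthetase family, of 0.39 (SE 0.12). In that list 0 members passed over all genes or adjusted over the list alone. Among macrophage markers, the lipoprotein component Apoe was at 0.76 (SE 0.15), the integrin chain Itgam at 0.64 (SE 0.14), the scavenger receptor Msr1 at 0.91 (SE 0.26) and the growth factor receptor Csf1r at 0.69 (SE 0.22). Adjusted over the list alone, 9 of 17 passed. Cd68 and Ctss, the markers of highest signal in that list, were at 0.19 and 0.23. Msr1, with a mean signal of 4.51, lay near the filter value of 4.33. Effector genes rose by 0.15 over 25 genes (camera adjusted p = 0.00145; adjusted p = 0.107 with an estimated correlation), among them the chemokines Ccl4 at 0.56 (SE 0.13) and Ccl3 at 0.52 (SE 0.15) and the cytotoxic protease Gzmb at 0.36 (SE 0.14). Of the effector genes, 1 passed when adjusted over the list alone. Of 4 settings for the value range, the effector call held in 1 (quantile normalization, camera adjusted p = 0.0400), and with the range as a covariate the rise was 0.09 (camera adjusted p = 0.204).

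In total 12 of 23 lists passed in this comparison, 11 up and 1 down, and 0 did with an estimated correlation. WT-host arrays 1 and 4 had a narrower range of values than the others, with slopes on the mean array of 0.956 and 0.934 against 0.989 to 1.04 in the remaining arrays, and genes of high signal move with such a slope. Under each of 4 settings that even out this difference or leave it out (quantile normalization, cyclic loess, the value range as a covariate, or the fit without these 2 arrays), the calls that held were those of the interferon gamma, type I interferon and macrophage lists. The other 9 calls were lost in at least 1 of the 4. They included, beside the effector list, T cell identity, T cell activation, naive and memory, proliferation, galectins and glycan branching, immediate early and heat shock, NK cell markers and, in the downward direction, tumor epithelium markers. The T cell identity list went from 0.14 to -0.01 with the value range as a covariate.

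Gene by gene, 0 of 15194 genes passed limma at an adjusted p under 0.05 in this comparison, while 1136 (7.48%) had an unadjusted p under 0.05 where 5% would by chance, 550 of them higher and 586 lower. Without the 2 arrays of narrowest range, 646 genes had such a p. Arrays of the 2 groups did not overlap for 8.89% of genes, where chance gives 5.71%. The genes of lowest p, none of which passed, included Ier3, an immediate early gene, at 0.89 (SE 0.18), the membrane protease Adam17 at 0.79 (SE 0.16), Megf11 at 1.99 (SE 0.39), Hook3 at 1.11 (SE 0.24), Snf8 at 0.65 (SE 0.13), Bpgm at 0.59 (SE 0.13) and the sialyltransferase St3gal1, which caps O-linked glycans of T cells, at 0.69 (SE 0.14). In the other direction were Dbndd1 at -1.50 (SE 0.23; adjusted p = 0.288), Ppp1r15b, which directs dephosphorylation of the translation factor eIF2 alpha, at -0.88 (SE 0.17), Gsdmcl1 at -1.26 (SE 0.26), Myog at -0.56 (SE 0.12) and Tnfrsf12a at -0.58 (SE 0.13). Rps15a-ps2, at 1.11 (SE 0.18), is named as a pseudogene of a ribosomal protein gene, so its signal cannot be assigned with certainty. The checkpoint receptors Lag3 and Pdcd1 were at -0.01 (SE 0.13) and -0.08 (SE 0.18), Cd8a at 0.09 (SE 0.11) and the sort marker Thy1 at -0.16 (SE 0.16).

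**Figure D2:**
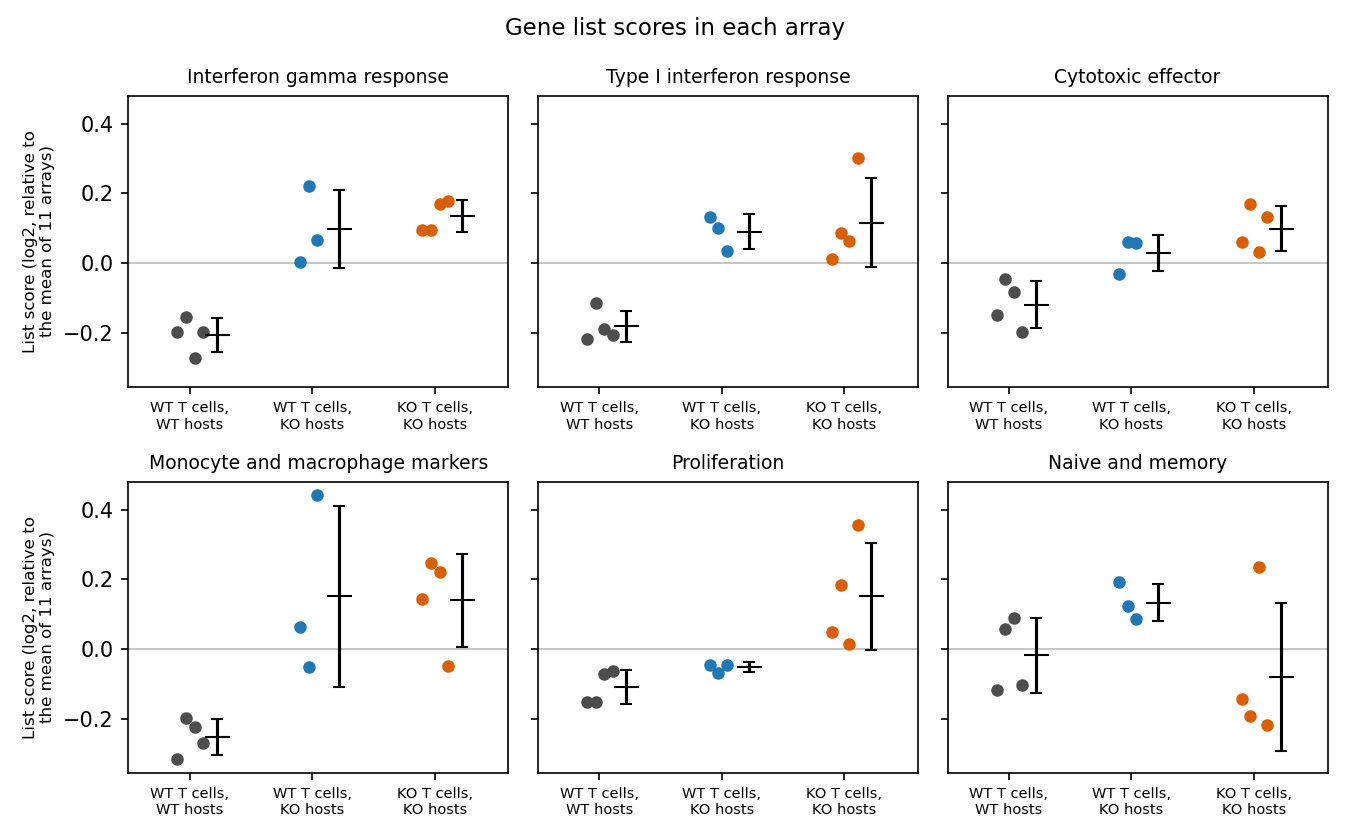
Score of 6 gene lists in each array (vertical axis, mean log2 signal of the list's measured genes relative to the mean of the 11 arrays), by group on the horizontal axis. Points are arrays, and the horizontal mark with its bar is the mean ± SD. The interferon gamma score was -0.21 ± 0.05 in WT T cells from WT hosts, 0.10 ± 0.11 in WT T cells from KO hosts and 0.13 ± 0.05 in KO T cells from KO hosts, while the proliferation score was highest in KO T cells, at 0.15 ± 0.15.

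Comparing KO T cells in KO hosts with WT T cells in WT hosts addressed loss of galectin-3 from both compartments. Proliferation genes rose by 0.26 on the log2 scale over 41 genes, 38 of them higher (camera adjusted p = 9.85e-12; adjusted p = 0.123 with an estimated correlation). The interferon gamma list rose by 0.34 with 16 of 17 genes higher (camera adjusted p = 3.23e-07; adjusted p = 0.0566 with an estimated correlation), and the type I interferon list by 0.30 with 21 of 24 higher (camera adjusted p = 1.41e-06; adjusted p = 0.0566 with an estimated correlation). Cytotoxic effector genes and cytokines rose by 0.22, with 19 of 25 higher (camera adjusted p = 8.95e-06; adjusted p = 0.0566 with an estimated correlation). Markers of some other cell types rose in the same arrays, those of monocytes and macrophages by 0.39 (camera adjusted p = 6.22e-08, and 0.107 with an estimated correlation). Lists of B cells, tumor epithelium, endothelium, stroma and CD4 T cells were lower, at -0.17, -0.14, -0.07, -0.05 and -0.03. Of these, tumor epithelium alone passed. Erythroid markers were at 0.06 and did not pass. NK cell markers rose by 0.54 over 6 genes (camera adjusted p = 0.000125; adjusted p = 0.0639 with an estimated correlation), by 0.34 without the 2 arrays of narrowest range (camera adjusted p = 0.0110) and by 0.33, no longer past the threshold, with the macrophage score as a covariate (camera adjusted p = 0.106). Dendritic cell and class II genes rose by 0.19 over 10 genes (camera adjusted p = 0.0472; adjusted p = 0.196 with an estimated correlation).

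Among proliferation genes, the kinetochore and spindle genes Cenpf, Kif20a, Cenpe and Kif2c had log2 fold changes of 0.66 (SE 0.13), 0.65 (SE 0.14), 0.62 (SE 0.14) and 0.54 (SE 0.15). In that list 8 members passed when adjusted over the list alone. Effector members included Ccl4 at 0.68 (SE 0.12), Ccl3 at 0.61 (SE 0.14), Gzmb at 0.46 (SE 0.13) and Ifng, the gene of interferon gamma, at 0.50 (SE 0.15). Adjusted over the list alone, 8 effector genes passed. Prf1, the gene of perforin, was at 0.30 (SE 0.14). In the interferon gamma list Cxcl9 was at 1.05 (SE 0.21), Gbp2 at 0.76 (SE 0.21), Gbp3 at 0.59 (SE 0.14) and Irgm1 at 0.56 (SE 0.14), with 5 past the threshold adjusted over the list alone. In the type I list Oasl2 was at 0.49 (SE 0.11), Parp14 at 0.55 (SE 0.17) and Usp18, a negative regulator of interferon signalling, at 0.43 (SE 0.12), with 2 past it. Of the macrophage markers, 9 passed adjusted over the list alone, with Csf1r at 0.89 (SE 0.20), Itgam at 0.63 (SE 0.13), Apoe at 0.60 (SE 0.14) and Adgre1 at 0.49 (SE 0.12). Adgre1, with a mean signal of 4.49, lay near the filter value of 4.33. The NK list contains Klre1 at 0.81 (SE 0.22) and the adaptor chains Tyrobp at 0.94 (SE 0.26) and Fcer1g at 0.43 (SE 0.14), which myeloid cells also use. The dendritic cell list owed its rise to class II genes, with Cd74 at 0.66 (SE 0.17), H2-Ab1 at 0.51 (SE 0.17) and H2-Aa at 0.51 (SE 0.17), and 3 members passed adjusted over the list alone. That list passed in 11 of 26 alternatives. Its call was lost with no filter on dim genes (camera adjusted p = 0.161), after median centring (camera adjusted p = 0.0547), with the macrophage score as a covariate (mean 0.11; camera adjusted p = 0.356) and without any 1 of 7 arrays, among them array 3 of WT T cells from WT hosts (camera adjusted p = 0.141), array 3 of KO T cells (camera adjusted p = 0.139) and array 2 of KO T cells (mean 0.14; camera adjusted p = 0.0983).

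Neutrophil markers as a list did not pass here (mean 0.38, median -0.02; camera adjusted p = 0.274), but did without a filter on dim genes (camera adjusted p = 0.0125). The calgranulins S100a8 and S100a9, abundant in neutrophils and monocytes, were at 2.72 (SE 0.55) and 1.10 (SE 0.23) and the receptor Csf3r at 0.67 (SE 0.18), and these 3 genes passed when adjusted over the list alone. The granule genes Elane, Mpo, Camp and Ltf were at -0.20, -0.01, -0.02 and -0.17. Mean signals of Mpo, Camp and Ltf were 4.52, 4.52 and 4.42, near the filter value of 4.33. Values so near it cannot decide on neutrophil RNA. The inhibitory receptor list did not pass (mean 0.05; camera adjusted p = 0.395), with Lag3 at 0.02 (SE 0.12) and Pdcd1 at 0.04 (SE 0.17). Cd8a and Thy1 were at 0.04 (SE 0.10) and 0.03 (SE 0.15). Of 23 lists, 11 passed in this comparison, 10 up and 1 down, and 0 did with an estimated correlation. The 7 rises named first held under all 4 settings for the value range, and the calls of the immediate early and heat shock, T cell identity, T cell activation and tumor epithelium lists were lost under each of them.

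At the level of single genes, 0 of 15194 passed limma at an adjusted p under 0.05, and 1285 (8.46%) had an unadjusted p under 0.05, 728 of them higher and 557 lower. Without the 2 arrays of narrowest range, 765 genes had such a p. Arrays of the 2 groups did not overlap for 5.02% of genes, where chance gives 2.86%. Pilra, an inhibitory receptor of myeloid cells, came closest at 1.02 (SE 0.13; adjusted p = 0.0580), beside Rps15a-ps2 at 1.21 (SE 0.16; adjusted p = 0.0580). Both passed with a filter at the 50th percentile (adjusted p = 0.0401) and with the mean of a gene's rows (adjusted p = 0.0387), and Pilra passed without array 4 of KO T cells (adjusted p = 0.0143). Next in order of p, and not past the threshold, were Frmd6 at 0.59 (SE 0.10), Ccl4, Shcbp1 at 0.89 (SE 0.16) and Depdc1a at 1.12 (SE 0.20), genes with roles in mitosis, Ier3 at 0.89 (SE 0.17), Cptp at 1.18 (SE 0.22), Fyco1 at 0.51 (SE 0.10) and Tlr13, an endosomal sensor of bacterial RNA, at 1.32 (SE 0.25). In the other direction, after Lgals3, were Cerox1 at -0.81 (SE 0.12), Cd209e at -0.62 (SE 0.10), Mxd4, an antagonist of Myc, at -0.57 (SE 0.11), Gm8225 at -0.71 (SE 0.15) and Ppp1r15b at -0.68 (SE 0.16).

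KO T cells were then set against WT T cells, both in KO hosts, which asked what the T cells' own galectin-3 changes. Proliferation genes rose by 0.20 on the log2 scale in KO T cells, with 39 of 41 genes higher (camera adjusted p = 1.17e-08; adjusted p = 0.196 with an estimated correlation). The naive and memory list fell by 0.21, with 13 of 16 genes lower (camera adjusted p = 0.00267; adjusted p = 0.320 with an estimated correlation), and neutrophil markers rose by 0.32, with 11 of 11 higher (camera adjusted p = 0.00720; adjusted p = 0.116 with an estimated correlation). Plk1, a mitotic kinase, had a log2 fold change of 0.53 (SE 0.17), Nusap1 of 0.39 (SE 0.17), Cenpe of 0.35 (SE 0.16) and Rrm1, a subunit of ribonucleotide reductase, of 0.27 (SE 0.13). Klf2, which maintains quiescence and lymphoid homing, was at -0.50 (SE 0.16), the homing receptor Ccr7 at -0.42 (SE 0.15) and Satb1 at -0.47 (SE 0.26). Against WT T cells in WT hosts, the naive and memory list was at -0.06 in KO T cells (camera adjusted p = 0.813). In WT T cells from KO hosts it was at 0.15 against that reference, a call lost under the settings for the value range. Adjusted over the list alone, 0 proliferation genes and 0 naive and memory genes passed, and 1 neutrophil gene did. S100a9 was at 1.02 (SE 0.25) and S100a8 at 1.54 (SE 0.59), while the other neutrophil markers were between 0.02 and 0.22. Array 4 of KO T cells had the highest proliferation score, and without it the list's mean was 0.14 (camera adjusted p = 0.000218). The naive and memory call was lost without array 2 of KO T cells (adjusted p = 0.0527), and the neutrophil call without array 2 of WT T cells from KO hosts (adjusted p = 0.0505) and with the filter at the 50th percentile, where its mean was 0.62 (adjusted p = 0.0968).

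The lists that were higher in KO hosts showed small differences between T cell genotypes within KO hosts, 0.04 for the interferon gamma list (camera adjusted p = 0.992), 0.03 for the type I interferon list (camera adjusted p = 0.774), -0.01 for macrophage markers (camera adjusted p = 0.785) and 0.07 for effector genes (camera adjusted p = 0.232). With 1 array left out, 3 of these had no stable sign. Macrophage markers ran from -0.11 without array 2 to 0.14 without array 3 of WT T cells from KO hosts, the interferon gamma list from -0.0088 without array 1 to 0.10 without array 2 of that group, and the type I list from -0.04 without array 4 to 0.06 without array 1 of KO T cells. Single genes passing limma numbered 0 of 15194, and 519 (3.42%) had an unadjusted p under 0.05, below the 5% of chance. Without array 3 of KO T cells, 818 genes had such a p, above the 760 that chance gives. Arrays of the 2 groups did not overlap for 4.07% of genes, where chance gives 5.71%. After Lgals3, the genes of lowest p included Pilra at 0.80 (SE 0.14), Mastl, a kinase that promotes mitotic entry, at 0.70 (SE 0.13), the histone methyltransferase Suv39h2 at 0.58 (SE 0.13), Tnfrsf12a at 0.58 (SE 0.13) and Yipf5 at 0.64 (SE 0.14) in the upward direction. Ston1 at -0.72 (SE 0.14), Inka1 at -1.17 (SE 0.24), Endog, a mitochondrial nuclease, at -0.83 (SE 0.18), Cdk9 at -0.68 (SE 0.17) and Cerox1 at -0.54 (SE 0.13) were lower, and none passed. Tnfrsf12a was lower by as much in the comparison between hosts. Both comparisons use the arrays of WT T cells from KO hosts, with opposite sign. A deviation of those arrays alone would give both of its values. Lag3 was at 0.02 (SE 0.13), Pdcd1 at 0.12 (SE 0.18), Ifng at 0.25 (SE 0.16), Gzmb at 0.10 (SE 0.14) and Prf1 at 0.11 (SE 0.16).

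The log2 fold changes of the 2 comparisons against WT T cells in WT hosts correlated across genes at r = 0.655, with a covariance of 0.0374. Both use the same 4 reference arrays, and simulated groups without any effect gave r = 0.464 and a covariance of 0.0166, so that the covariance exceeded the simulated one by 0.0208. With the reference arrays split 2 and 2 between the comparisons, r averaged 0.223. The simulated genes vary independently, whereas the first principal component of the real arrays followed their value range (r = 0.967). Arrays 1 and 4 of the reference group were narrow in range, which the simulation lacks. The excess therefore need not be an effect shared by the comparisons. Genes are not independent replicates, and no p is given for these correlations.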

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

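The same criterion was applied to every group of 4, but most genes tested had been named for a low p between groups in these same data. The groups of 4 arrays numbered 474. They were made of list scores, the value range and 213 genes picked by the rule for named genes, not all printed here. In 24 of them 1 array lay far from the other 3. The criterion was Dixon's at 95%, on the gap to the nearest array divided by the group's range, which is the value given below. Chance gives about 1 in 20 such groups where they are not chosen by their values, and 24 of 474 is no more than that.

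In KO T cells, array 3 stood apart in the naive and memory list, with a score of 0.24 against -0.22 to -0.14 in the others (0.833). It was also higher for the naive and memory genes Bcl2 (0.878) and Slamf6 (0.843). It was lower in the tumor epithelium list (0.904) and for Col5a1 (0.923). Without this array, the naive and memory list differed between T cell genotypes in KO hosts by -0.32, against -0.21 with it. Array 4 of KO T cells was lower for Uhrf1, which maintains DNA methylation during replication (0.964), and higher for Epcam (0.964). Array 2 was lower for the migration receptor Gpr183 (0.938), and array 1 for 1110002L01Rik (0.965).

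In WT T cells from WT hosts, array 3 was lower for Ier3 (0.878), Prf1 (0.917), Lgals3bp (0.960) and Usp18 (0.880). The same array was higher for Rrm1 (0.950) and Ier2 (0.833). Array 1 was lower in the list of chemokine receptors, integrins and homing (0.856). It was higher for Gbp3 (0.882), Bcl2 (0.882), Fyco1 (0.839) and 1600019K03Rik (0.866). Array 4 was higher for Adm (0.895), Col6a1 (0.836) and Tpi1 (0.843), and array 2 for Cptp (0.922).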

How the results depend on the processing

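Chosen after the data were seen were cyclic loess, the 3 covariates and the fit without the 2 arrays of narrowest range. A planned surrogate variable was not run, and a residual component stood in for it. In both comparisons of KO T cells, Lgals3 stayed lower under every alternative and passed limma's threshold in none. Genes past the threshold numbered 0 under every alternative for WT T cells between hosts and for T cell genotypes in KO hosts. For both genotypes together, 2 passed with the filter at the 50th percentile and 2 with the mean of a gene's rows, Pilra and Rps15a-ps2 each time. With 1 array left out, 0 to 1 passed. Replicate numbers gave no clear sign of pairing, with 2 of 10 same-numbered pairs correlated over 0.1. Their mean r was 0.022, against -0.0075 for pairs with different numbers. A shared day, litter or batch cannot be excluded by these values. With the numbers as a block, 3 genes passed, S100a8 being the third.

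The Lgals3 difference between hosts in WT T cells, -0.03, passed no threshold and had no stable sign. It was 0.0212 after median centring, 0.00082 with array weights, 0.0030 with the replicate block, 0.154 with the value range as a covariate and 0.112 without the 2 narrow arrays. With 1 array left out it ran from -0.120 to 0.0942.

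Lists past the threshold numbered 12 between hosts, 11 for both genotypes together and 3 between T cell genotypes. The first 2 counts were 4 and 7 after quantile normalization, 3 and 7 with cyclic loess, 3 and 7 with the value range as a covariate, and 3 and 7 without the 2 narrow arrays. They were 4 and 7 with the macrophage score as a covariate, which leaves the macrophage list itself untested. The first was 7 with the filter at the 50th percentile. All 3 counts were 0 with an estimated correlation, which reached 0.384 against the preset 0.01. By fry they were 3, 6 and 0. The T cell identity list reversed with the value range as a covariate, to -0.0108 between hosts and -0.0176 for both genotypes. The correlation of the comparisons that share the reference arrays was 0.223 with these arrays split, which removes the sharing. Over all alternatives, calls of single lists were lost in 146 cases beside the 2 reversals and gained in 25, and calls of named genes were gained in 8 and lost in 0. For these and the remaining changes the cause was not tested. Signal over background is not given in the deposited values, so its limits were not measured.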

Other observations

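The tests of the value range, of the share of T cells and of macrophage against dendritic cell scores were chosen only after the results were seen. The chemokine receptor Cxcr4 was at -0.43 (SE 0.16) on the log2 scale in KO T cells from KO hosts against WT T cells from WT hosts, and at -0.42 (SE 0.18) against WT T cells from KO hosts. Its homing list passed in neither (camera adjusted p = 0.925 and 0.733). The matrix gene Fn1 was at 0.83 (SE 0.23) in WT T cells and 0.74 (SE 0.21) in KO T cells from KO hosts against the reference group. Its stromal list was at -0.06 and -0.05 (camera adjusted p = 0.232 and 0.25). The glucose transporter Slc2a3 was at 0.47 (SE 0.18) in KO against WT T cells in KO hosts, in a glycolysis list at 0.05 (camera adjusted p = 0.395). Mgat5, which branches N-glycans, was at -0.76 (SE 0.50) in that comparison, in a list at -0.10 (camera adjusted p = 0.175). B cell markers were at -0.17 in KO T cells from KO hosts against the reference (camera adjusted p = 0.128), with Jchain at -0.77 (SE 0.36). That list was at -0.28 and passed without array 3 of WT T cells from WT hosts (camera adjusted p = 0.0173), was at -0.06 without array 4 of that group, and passed without array 1 of KO T cells (camera adjusted p = 0.0490) and with the macrophage score as a covariate (camera adjusted p = 0.0215). Under the 4 settings for the value range it passed in none and ran from -0.14 to 0.04. Oxidative phosphorylation was at 0.08 between hosts (camera adjusted p = 0.0560), passed in 8 of 26 alternatives, and was at 0.0027 to 0.02 under the settings for the value range (camera adjusted p from 0.826 to 0.969). For both genotypes together it was at 0.05 (camera adjusted p = 0.162) and passed in 2 alternatives. It was at -0.02 to -0.0068 under the settings for the value range, and at 0.01 without array 4 and 0.09 without array 1 of KO T cells. Lists of CD4 and regulatory T cells, endothelium and erythroid cells passed in no comparison, and none of the genes named here passed.

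Of 146 tested genes within 10 Mb of Lgals3, 0 passed in any comparison. Between hosts, 10.3% of them had an unadjusted p under 0.05 against 7.45% of other genes (Fisher's exact test p = 0.204). For both genotypes together the shares were 12.3% and 8.41% (Fisher's exact test p = 0.0986). Psme1, of the proteasome activator, was lowest in p there, at 0.42. Between T cell genotypes in KO hosts the shares were 4.79% and 3.4% (Fisher's exact test p = 0.352), with Ripk3 lowest in p, at 1.05. In the same order, fry for change in either direction gave 0.151, 0.00104 and 0.694, which does not compare these genes with others. Camera, which does, gave unadjusted p of 0.122, 0.0324 and 0.467.

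The arrays of each comparison were also split in the other ways possible. Between hosts, 1 of 35 splits, the real one, gave as many as 12 lists past the threshold, with 11 the highest other. This is the smallest share that 35 splits allow, and it is not adjusted for the other counts split here. Both arrays of narrowest range lie in the WT-host group, so the split cannot tell genotype from that structure. After quantile normalization 5 of 35 splits reached the real 4, with 6 the highest other. Chance is not excluded for either count. For both genotypes together, 2 of 35 splits gave as many as the real 11 lists, with 11 the highest other. Between T cell genotypes, 16 of 35 gave as many as the real 3, with 6 the highest other. After quantile normalization, 2 of 35 reached the real 7 and 7 of 35 the real 3, with 7 and 4 the highest others. Chance cannot be excluded for these counts. Genes at an unadjusted p under 0.05 were as many in 7 of 35 splits between hosts (1136, highest other 1957) and in 6 of 35 for both genotypes (1285, highest other 1554). Between T cell genotypes they were as many in 27 of 35 (519, highest other 1551). Nor can it be for these, and the higher counts of other splits point to a structure of the arrays apart from the groups. The real count of genes past the threshold was 0 in each comparison, which any split reaches by definition (35 of 35). That share therefore says nothing about chance. The highest counts in other splits were 0, 1 and 1.

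Interferon and effector lists were higher in KO hosts, and their medians between hosts lay at percentile 99.85 (interferon gamma), 100 (type I) and 99.22 (effector) of random lists matched on signal. This argues against the narrow value range as the source of the interferon rises, whose calls held with that range as a covariate, and of the effector rise for both genotypes together (percentile 99.67), which held under all 4 settings for the range at 0.16 to 0.18. Between hosts the effector call was lost in 3 of the 4 settings, with cyclic loess (camera adjusted p = 0.0911), without the 2 narrow arrays (0.0728) and with the range as a covariate (0.204), where the rise went from 0.15 to 0.09, so that there range and genotype cannot be told apart. With the macrophage score as a covariate, the interferon gamma rise for both genotypes together was 0.413 (SE 0.0766), against 0.34 without it. The type I rise was 0.417 (SE 0.0882), against 0.30. Macrophage scores did not overlap between host genotypes, so the covariate rests on the relation within groups. There r was -0.416 for interferon gamma and -0.546 for type I. That argues against macrophage RNA in proportion to its markers as the whole source of these rises. It cannot address macrophage RNA that differs in interferon genes between hosts. A response to hosts without galectin-3, which may account for the rises, stays a hypothesis that no list call with an estimated correlation backs. By fry, which does not compare a list with other genes, the interferon gamma and type I lists passed between hosts (fry adjusted p = 0.0201 and 0.0443). For effector genes the rise for both genotypes together was 0.195 (SE 0.0751) with the macrophage score as a covariate, against 0.22. Their call there held in 25 of 26 alternatives, this covariate among them. Between hosts the rise with it was 0.124 (SE 0.0787), against 0.15. Within groups the effector score had r = 0.150 to the macrophage score over 11 arrays (exact one-sided permutation p = 0.354). With that sign and the uncertain rise between hosts, macrophage RNA cannot be told apart from a change in the T cells.

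Macrophage markers were higher in KO hosts, although the sort on Thy1.2 would remove such cells, and random lists matched on signal argue against the value range (percentile 100). If other cells entered the sort alike, a lower share of T cells would raise all their markers. Macrophage markers rose by 0.547 (SE 0.158) more than tumor epithelium markers between hosts. The tumor epithelium list lay at percentile 28.6 of signal, against 63.1 for the macrophage list. Its own fall, part of that difference, was lost under all 4 settings for the value range. The difference therefore cannot decide on a lower share of T cells. Carried-over monocyte or macrophage RNA could give the rise and stays open, since the macrophage and dendritic cell scores correlated within groups at r = 0.359 over 11 arrays (exact one-sided permutation p = 0.136). The markers of highest signal, Cd68, Ctss and Apoe, with mean signals of 8.79, 8.76 and 7.92, were at 0.19, 0.23 and 0.76. The host genotype also stays open, untested, and without array 3 of WT T cells from KO hosts the rise was 0.26 in place of 0.40.

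Proliferation genes were higher in KO than in WT T cells within KO hosts. Mean slopes on the mean array were 1.013 in KO and 1.016 in WT T cells there, so the value range hardly differed. Leaving out array 4 of KO T cells lowered the mean most, from 0.20 to 0.136, so 1 array does not carry the whole difference. The scores did not overlap, at 0.015 to 0.356 in KO T cells and -0.070 to -0.045 in WT T cells. Their exact two-sided permutation p was 0.0857, so chance stays open. The T cells' own galectin-3 is a candidate explanation that was not tested further.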
